A study of Mus musculus with 16 samples.

How the data were processed

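Messenger RNA of HM1 tumours, a mouse ovarian cancer model, was measured by bulk RNA sequencing in 16 libraries. Of these, 10 came from whole tumour tissue (5 control, 5 with mannose supplementation) and 6 from CD8 T cells sorted out of such tumours (3 control, 3 with mannose). The authors deposited 1 table per library, with gene symbols and a single column of TPM, transcript abundance scaled to a common total per library, in each. The unit was read from the values, which had 2 decimals and summed to between 993815 and 997809 per library. The submitters' processing notes name fastp, HISAT, RSEM and the genome build GRCm39 without versions or the part each played, and the annotation release is not stated. Because the annotation at hand follows an older build, no gene coordinates are given.

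The tumour tables hold 54013 entries under 53112 symbols and the CD8 tables hold 55438 entries under 55290 symbols. Entries that shared a symbol were summed. TPM values carry no library totals, so the read depth of each library is unknown and no interval for counting error can be given. The number of symbols with at least 1 TPM, from 12345 to 13820 in the tumours and from 13538 to 14384 in the CD8 libraries, was taken as the only view of depth. Predicted genes and pseudogenes, counted together with immunoglobulin and T cell receptor segment genes, held between 11.5% and 15.1% of the TPM.

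Groups were taken from the sample labels. The value columns of all 3 CD8 control tables are headed as mannose samples, as are those of the 3 CD8 mannose tables; the labels were followed. Differences between mannose and control were tested in each tissue separately with limma 3.58.1 in R 4.3.3, with its variance trend, on log2(TPM + 1), for genes with at least 1 TPM in as many libraries as the smaller group holds. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A count model had been laid down for tables of counts; the limma test was the choice laid down for TPM. The difference between the mannose effect in the CD8 libraries and that in tumours was tested as an interaction in a fit of all 16 libraries. That fit covered 52916 shared symbols, for genes with at least 1 TPM in 3 libraries. Labels do not state which animals the replicates came from.

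The comparisons, the tests, 40 gene lists with 595 genes, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover T cell function, immune signalling, metabolism, stress, matrix, signs of RNA quality and the markers of other cell types. Of the 595 genes, 4 were absent under the listed symbol and 2 of these were matched by a synonym. Lists with at least 5 tested genes were compared with all other genes by limma's camera with its preset correlation of 0.01, then with a correlation estimated from the data. Limma's fry tested whether the genes of a list moved in 1 direction, or in either direction, without comparing them with other genes. The level of a list in a library is the mean log2(TPM + 1) of its genes, and levels were compared between groups by 2-sided exact permutation tests. Genes named are the 10 with the largest rise and the 10 with the largest fall past the threshold, at a mean of at least 5 TPM and with predicted, immunoglobulin and receptor segment genes left out. Where fewer than 5 passed, the 5 with the smallest p in each direction were named as not passing. Up to 4 members of each list past the threshold, a panel of 12 genes and the 5 genes with the smallest p of the interaction were named as well. Calls shared between the tissues were counted with Fisher's exact test, 2-sided.

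The fits were tested on simulated data built from these libraries, in which genes were moved by a known fold. In the tumour fit 46% of genes moved 1.5-fold, 62% of those moved 2-fold and 98% of those moved 4-fold were called, with 4 false calls among 13120 genes. In the CD8 fit these shares were 32%, 64% and 90%, with 5 false calls among 13961 genes. In the interaction fit they were 18%, 42% and 88%, with 8 false calls among 15148 genes. A list moved 1.74-fold was called in both tissues. Noise was drawn for each gene and library on its own, so the simulation held no correlation between genes and no like pairs of libraries. Its shares and false calls do not cover these. Other groupings of the real libraries called a median of 11 lists in the tumours and 10 in the CD8 libraries.

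Alternatives changed 1 choice at a time: the pseudocount, the filter on low values, quantile normalization, the replicate number as a block, genes of high and variable share left out, all libraries in 1 fit, and each library left out in turn. Added after the data were seen were median-ratio scaling, limma's array weights, leaving out the 2 tumour libraries that stood apart, scaling the CD8 libraries to their T cell markers, and averaging the CD8 libraries that shared their T cell receptor V segment use. Figures were drawn with matplotlib 3.10.9 in Python 3.11.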

Results

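Bulk RNA sequencing was carried out on HM1 tumours, a mouse ovarian cancer model, with or without supplementation of mannose, a simple sugar. Whole tumour tissue gave 5 control and 5 mannose libraries, and CD8 T cells, the cytotoxic T cells that infiltrate tumours, were sorted for 3 control and 3 mannose libraries. Values are TPM, and errors are standard deviations between libraries. Read depth is unknown, and between 12345 and 14384 symbols reached 1 TPM in a library. The labels do not say which animals the replicates came from, so p-values measure the spread between these samples. They also do not say whether an antibody against PD-1, named in the title of the series, was given.

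The comparison of mannose with control in whole tumours asked how the supplement changed expression in the tissue. As groups, T cell effector genes, macrophage markers and cell cycle genes rose relative to all other genes by a set test with a preset correlation. Skeletal muscle, carcinoma, erythroid and mast cell markers, glycolysis genes and ribosomal protein genes fell. These list calls were lost with an estimated correlation, and no single gene passed the threshold. By exact permutation tests of list levels between tumours, effector genes (p = 0.183), macrophage markers (p = 0.135) and cell cycle genes (p = 0.175) did not differ. Nor did the lists named as falling, with p from 0.190 for muscle to 0.849 for glycolysis in the same test. Gzmb, which encodes the cytotoxic protease granzyme B, measured 15.9 ± 10.2 TPM in control and 42.2 ± 33.0 TPM in mannose tumours (SD, n = 5 each), a log2 difference of 1.24 that did not pass (adjusted p = 0.754). Mrc1, the macrophage mannose receptor, measured 33.9 ± 9.34 and 52.9 ± 10.8 TPM, a log2 difference of 0.65 that did not pass (adjusted p = 0.754). Both genes were above every control in 3 of the 5 mannose tumours. By limma, 0 of 13282 genes passed (smallest adjusted p = 0.754). An unadjusted p under 0.05 was found for 827 (735 higher and 92 lower) against 664.1 expected by chance. The excess of rises depended on the scaling, with 303 higher and 441 lower after quantile normalization and 426 higher and 341 lower after median-ratio scaling. Array weights gave 1618 genes (1297 higher and 321 lower), no filter on low values 1454 of 28390, and all 16 libraries in 1 fit 1247. Leaving out control 1 gave 671 higher and 216 lower, and leaving out mannose 5 gave 567 in all. The groups did not overlap for 217 genes, or 1.63%, against a chance share of 0.794%. The median log2 difference of all genes was 0.12, with -0.005 after quantile normalization, 0.02 after median-ratio scaling and 0.02 without control 1, so list changes below are relative to that median. Leaving out mannose 4 raised the count to 1 gene, the small RNA Rny3, listed at 0 in all controls and in mannose 4. Its values in the other mannose tumours were 72.1, 77.0, 71.0 and 25.8 TPM.

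Of the 15 tested T cell effector genes, 14 had a higher mean with mannose, with a median log2 difference of 0.66 (camera adjusted p = 0.00183). That call was lost with mannose 3 left out (adjusted p = 0.0799), and adjusted p = 0.817 with an estimated correlation. Prf1, which encodes the pore-forming perforin, measured 8.92 ± 7.48 and 18.8 ± 16.4 TPM (SD, n = 5) and did not pass. Without both control 1 and mannose 3, the libraries that stood apart, adjusted p was 0.105 for the effector list and 0.325 for macrophage markers. Their medians relative to all genes were then 0.21 and 0.06. Macrophage and monocyte markers had a median of 0.49 with 13 of 14 positive (adjusted p = 0.00418), lost without mannose 3 (adjusted p = 0.169). For these, adjusted p = 0.817 with an estimated correlation. All 23 cell cycle genes were positive, with a median of 0.23 (adjusted p = 0.00252), and adjusted p = 0.818 with an estimated correlation. The cell cycle call was lost without control 2 (adjusted p = 0.0705), control 4 (adjusted p = 0.0525) or mannose 2 (adjusted p = 0.0534). Mki67, a marker of dividing cells, measured 14.6 ± 5.61 and 18.2 ± 1.64 TPM and did not pass. In none of these 3 lists did a member pass by limma over all genes or adjusted over the list alone, and 38 of the 512 list genes tested in the tumours had an unadjusted p under 0.05.

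Medians of the lists that fell ranged from -1.45 to 0.02. Skeletal muscle markers had a median log2 difference of -1.45, with 7 of 7 negative (adjusted p = 9.94e-08), and adjusted p = 0.817 with an estimated correlation. This was the 1 list of 12 that kept its camera call in each alternative with the preset correlation. Muscle levels ranged from 0.385 to 5.17 between single tumours, and the mannose mean of 1.90 ± 1.68 against 3.33 ± 1.39 in controls (SD, n = 5) did not differ by an exact permutation test (p = 0.190). Erythroid markers had a median of -0.47 (adjusted p = 0.0106), mast cell markers -0.35 (adjusted p = 0.0219) and carcinoma keratins and other epithelial markers -0.24 (adjusted p = 0.00134), each with adjusted p = 0.817 with an estimated correlation. Glycolysis genes had a median of -0.07 (adjusted p = 0.00148), ribosomal protein genes, a sign of library quality, -0.06 (adjusted p = 4.45e-07), endothelial markers -0.02 (adjusted p = 0.0425) and immediate-early genes, which rise when tissue is dissociated, -0.01 (adjusted p = 0.00973). Each of these 4 had adjusted p = 0.817 with an estimated correlation. The unfolded protein response list fell relative to other genes (adjusted p = 0.0288) although its median of 0.02 and mean of 0.002 were positive, and adjusted p = 0.817 with an estimated correlation. Only the muscle and carcinoma calls were kept with each library left out in turn. The carcinoma call was lost with no filter on low values (adjusted p = 0.114, median relative to all genes -0.03), after quantile normalization (0.0563), with array weights (0.178) and without control 1 and mannose 3 together (0.106). Quantile normalization also ended the erythroid, mast cell, glycolysis, ribosomal, endothelial, immediate-early and unfolded protein calls (adjusted p from 0.0563 to 0.720). The lack of a filter ended the erythroid, mast cell, endothelial, immediate-early and unfolded protein calls (at least 0.0798), median-ratio scaling the erythroid, mast cell and endothelial calls (0.0606 to 0.193), and array weights the glycolysis and unfolded protein calls (0.182 and 0.136). The ribosomal call was lost without control 1 (adjusted p = 0.234) and the glycolysis call without control 5 (adjusted p = 0.205). The erythroid call was lost without control 1 (adjusted p = 0.0604), control 4 (0.158), mannose 1 (0.242) or mannose 2 (0.0674). The mast cell call was lost without control 4 (adjusted p = 0.0843), control 5 (0.0934), mannose 1 (0.136) or mannose 2 (0.0529). The immediate-early call was lost without control 2 (adjusted p = 0.107) or mannose 5 (0.0968), and the unfolded protein call without control 4 (0.0547), control 5 (0.0871), mannose 3 (0.0704) or mannose 5 (0.0803). The endothelial call was lost without control 2 (adjusted p = 0.153), control 3 (0.257), control 4 (0.0628), mannose 2 (0.129), mannose 5 (0.0580) or mannose 1, where its median relative to all genes turned to 0.004 (adjusted p = 0.530). With an estimated correlation 0 of 34 lists passed and 1 had an unadjusted p under 0.05. Fry's test of change in 1 direction called 0 lists, also at an unadjusted p, and its test of change in either direction called 1, given below.

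The lists that follow did not pass in the tumours, though some did under alternatives given below. T cell markers had a median of 0.38 (camera adjusted p = 0.286), CD4 and regulatory T cell markers 0.32 (adjusted p = 0.0995), exhaustion genes 0.21 (adjusted p = 0.317), interferon-gamma-induced genes 0.42 (adjusted p = 0.698) and extracellular matrix genes 0.62 (adjusted p = 0.108). Memory, type I interferon and MHC class I genes had positive medians of 0.06, 0.05 and 0.08 and camera directions of down, with adjusted p of 0.542, 0.0892 and 0.291. For NF-kappaB inflammatory genes the median was 0.12, and fry's test of change in either direction gave an adjusted p of 0.00913. Adjusted over the list alone, 4 of its 17 members rose and 2 fell, against 0 over all genes. The members, named after their values were seen, were the cytokines Il6 (1.03 ± 0.311 to 2.20 ± 0.240 TPM, n = 5), Il1a and Tnf and the monocyte chemokine Ccl7 among those that rose, and the neutrophil chemokines Cxcl3 (208 ± 33.2 to 142 ± 44.4 TPM) and Cxcl5 among those that fell. Arg1, an arginine-degrading enzyme of suppressive macrophages, rose from 125 ± 29.6 to 256 ± 106 TPM as 1 of 15 checkpoint and suppressive genes adjusted over the list alone, against 0 over all genes (adjusted p = 0.754), and that list had a median of 0.26 (adjusted p = 0.294). Among 8 neutrophil markers, Mmp9 rose and S100a8 fell adjusted over the list alone, against 0 over all genes; the median was -0.03 (adjusted p = 0.0892). Of 19 alternatives, type I interferon genes passed with negative medians relative to all genes in 6. These were array weights (adjusted p = 0.00906), the removal of control 3 (2.54e-04), control 4 (0.0374), mannose 1 (0.0429) or mannose 3 (1.23e-07), and that of control 1 and mannose 3 together (2.16e-05). MHC class I genes passed, also negative, without control 4 (0.0461), mannose 3 (5.71e-04) or control 1 and mannose 3 (0.00822), and neutrophil markers, also negative, with array weights (0.0293) or without control 3 (0.0184), mannose 3 (0.0298) or mannose 4 (0.0453). Matrix genes passed with positive medians after quantile normalization (5.52e-04) or median-ratio scaling (0.0197), with the replicate number as a block (3.63e-04) and without control 3 (0.00285) or mannose 1 (0.0429). CD4 markers passed, also positive, with the block (0.00933), median-ratio scaling (0.0241) or array weights (0.00906) and without control 3 (0.00285). Interferon-gamma-induced genes passed as positive without control 5 (0.0413) or mannose 5 (0.0411) and as negative without mannose 3 (median relative to all genes -0.18, adjusted p = 0.0308). T cell markers passed after median-ratio scaling (0.0438) and checkpoint genes without control 5 (0.0241), both positive. Memory, exhaustion and inflammatory genes passed in 0 of the 19.

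Genes with the smallest p in the tumours did not pass either, all with an adjusted p of 0.754. On the higher side were Fastkd3, a mitochondrial RNA-processing factor (6.01 ± 0.902 and 10.0 ± 1.55 TPM, n = 5), Appl1, an endosomal adaptor (4.10 and 6.95 TPM), Ms4a4a, a macrophage membrane protein (21.3 ± 6.62 and 38.6 ± 4.15 TPM), Npl, a sialic acid lyase (18.3 and 32.7 TPM), and Adamdec1, a metalloprotease of macrophages (7.06 and 17.0 TPM). On the lower side were Hcfc1r1 (102 ± 15.3 and 74.5 ± 6.44 TPM), the epoxide hydrolase Ephx1 (60.1 and 42.2 TPM), the matrix protein Efemp1 (37.4 and 26.6 TPM), the mitochondrial malic enzyme Me3 (13.9 and 9.52 TPM) and the transcription factor Jund (126 and 98.9 TPM). Of the fixed panel, Cd8a measured 1.29 and 2.15 ± 3.03 TPM, Pdcd1, the gene of PD-1, 2.67 ± 2.15 and 3.20 ± 3.31 TPM, and Cd274, the gene of its ligand, 10.7 ± 6.10 and 14.9 ± 9.67 TPM. Tcf7 measured 18.2 and 18.6 TPM, Il7r 1.21 and 1.88 TPM, and Mpi, the enzyme that feeds mannose into glycolysis, 13.5 and 14.0 TPM. Ifng (0.312 and 0.688 TPM) and Tox (0.216 and 0.356 TPM) were too low to be tested. The sign of the Pdcd1, Tcf7 and Mpi differences turned under quantile normalization (-0.09, -0.09 and -0.06 on the log2 scale), none of them past the threshold. Control 1 had the lowest mean correlation with the other tumour libraries (0.947).

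**Figure D1:**
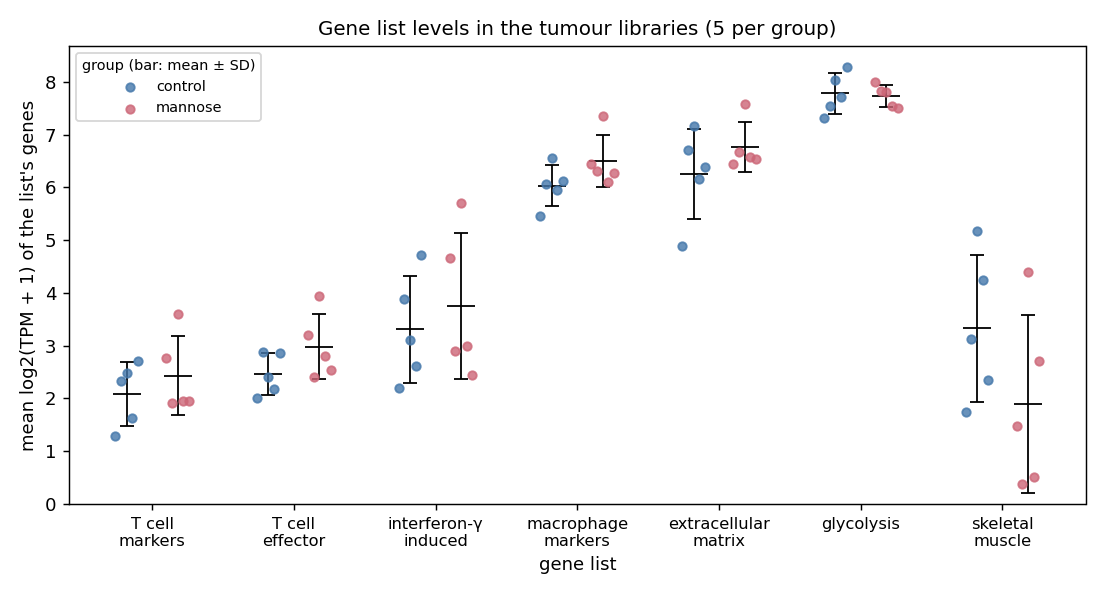
Each point is the mean log2(TPM + 1) of a gene list in 1 whole tumour library, by list on the x axis, with bars for mean ± SD of 5 control and 5 mannose tumours. The muscle level runs from 0.385 to 5.17, and the effector means are 2.47 in control and 2.98 with mannose.

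In sorted CD8 T cells, mannose was compared with control to ask how the supplement changed the T cells of the tumour. The value columns of all 3 control tables were headed as mannose samples, as were those of the 3 mannose tables, so each direction given here rests on the sample labels. As mean levels of their lists, macrophage markers, MHC class II genes and inflammatory genes were lower in every mannose library than in every control library, and epithelial markers and matrix genes were higher. As medians of the lists' genes the epithelial difference was 0.0057 on the log2 scale (exact permutation test, p = 1), while the other 4 kept theirs, so the epithelial rise rested on some of its 12 genes. Single members went the other way, such as the epithelial cadherin Cdh1 and the matrix gene Thbs1, which fell. The arginine-degrading enzyme Arg1 fell from 942 ± 33.5 to 154 ± 29.1 TPM (SD, n = 3 each), a log2 change of -2.62 (adjusted p = 2.03e-04). The inflammatory cytokine Il1b fell from 1903 ± 120 to 359 ± 52.9 TPM and the macrophage growth factor receptor Csf1r from 178 ± 15.3 to 46.7 ± 4.58 TPM. Krt8, a keratin of carcinoma cells, rose from 172 ± 70.8 to 876 ± 190 TPM, a log2 change of 2.42 (adjusted p = 0.00331). T cell genes were lower too, with the PD-1 gene Pdcd1 falling from 739 ± 77.7 to 421 ± 156 TPM and Gzmb from 2907 ± 176 to 1476 ± 690 TPM, calls that single libraries decided. Mitochondrial genes held 3.93% to 4.43% of the TPM in control and 4.61% to 5.11% in mannose libraries.

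By limma, 3306 of 14280 genes rose and 1674 fell, 1425 and 621 of them at least 2-fold. The groups did not overlap for 7334 genes, or 51.4%, against a chance share of 10%. That chance share takes all libraries as independent samples, which the like pairs given below leave in doubt. Of the calls, 66.4% were rises, against 53.7% after quantile normalization (2673 up, 2305 down) and 54.0% after median-ratio scaling (2731 up, 2328 down). Leaving out mannose 1 gave 2040 rises and 1028 falls, leaving out mannose 2 gave 1909 and 894, and leaving out control 2 gave 2401 and 1048. Control 1 and 2 shared their use of T cell receptor beta chain V segments, as did mannose 1 and 2. With each such pair averaged into 1 library, 1091 genes rose and 561 fell, 1080 and 549 of them also called with all libraries. Of 148 calls of named genes and list members, 68 were lost that way, 39 with all 16 samples in one fit (2659 rises and 1263 falls), 27 with no filter on low values, 14 after quantile normalization and 7 after median-ratio scaling. Array weights gave 5114 and 3517, and scaling each library to its T cell markers, which raised the median of all genes to 0.72, gave 6876 and 384.

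Among the 10 largest rises past the threshold, Tenm4, a teneurin adhesion protein, rose from 6.21 ± 4.57 to 52.4 ± 13.4 TPM (log2 3.05, adjusted p = 0.00319), the tight junction gene Cldn2 from 14.1 to 103 TPM, the matrix glycoprotein gene Tnr from 3.85 to 32.5 TPM and the small heat-shock protein gene Hspb1 from 31.1 to 256 TPM. Tmem200a, Ctnnal1, the amino acid transporter gene Slc38a4, Baiap2l1 and Thsd4 rose by log2 values between 2.67 and 2.84. Tff2, a secreted trefoil peptide, rose from 2.04 to 27.3 TPM (adjusted p = 0.0307), a call that was lost without each library but mannose 3 (adjusted p up to 0.110), with like libraries averaged and with no filter on low values (adjusted p = 0.0784). Among the 10 largest falls, the chemokine gene Ccl24 fell from 1687 ± 166 to 216 ± 47.5 TPM (log2 -2.98, adjusted p = 2.22e-04), the Fc receptor gene Fcgr1 from 77.9 to 9.70 TPM, the chitinase-like gene Chil3 from 49.6 to 5.84 TPM and the serpin gene Serpinb2 from 62.9 to 8.69 TPM. Scimp, the coagulation factor gene F10, the costimulatory receptor gene Cd40, Slfn4 and the antiviral gene Rsad2 fell by log2 values between -2.71 and -2.63.

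All 14 macrophage markers fell, over all genes and adjusted over the list alone, with a median log2 change of -1.82 (camera adjusted p = 7.61e-13), and adjusted p = 0.223 with an estimated correlation. Mrc1 fell from 204 ± 11.3 to 43.5 ± 9.34 TPM, the complement gene C1qc from 337 to 101 TPM, the lysosomal marker gene Cd68 from 287 to 75.1 TPM and the lipopolysaccharide co-receptor gene Cd14 from 682 to 161 TPM. All 11 MHC class II genes tested fell both ways of adjusting, with a median of -1.78 (adjusted p = 4.49e-12), and adjusted p = 0.230 with an estimated correlation. H2-Aa fell from 1071 to 238 TPM and H2-Ab1 from 762 to 160 TPM. Of 18 NF-kappaB inflammatory genes 15 fell, 16 fell and 1 rose adjusted over the list alone, with a median of -1.27 (adjusted p = 1.95e-10), and adjusted p = 0.223 with an estimated correlation. Il1a fell from 188 to 36.3 TPM and Ptgs2, the gene of the prostaglandin-forming COX-2, from 197 to 73.4 TPM. Neutrophil markers fell in 7 of 8 both ways (median -1.55, adjusted p = 9.21e-06), and adjusted p = 0.223 with an estimated correlation, with the interleukin-1 decoy receptor gene Il1r2 going from 321 to 69.4 TPM. Dendritic cell markers fell in 5 of 8, and 6 adjusted over the list alone (median -0.74, adjusted p = 0.00313), and adjusted p = 0.223 with an estimated correlation. The members Zbtb46, Flt3, Ccl22 and Clec9a were lost with like libraries averaged and when scaled to the T cell markers. They were also lost without a single library: Zbtb46 without mannose 1 or 2 (adjusted p up to 0.0530), Flt3 without control 1 or 2 or mannose 1 (0.0760), Ccl22 without control 1, 2 or 3 or mannose 2 (0.0634), and Clec9a without control 2 or 3 or mannose 1 or 2 (0.0776). Ccl22 and Clec9a were lost with no filter on low values too (0.0517 and 0.0521). Checkpoint ligand and suppressive genes fell in 10 of 15 and rose in 3, 11 and 3 adjusted over the list alone (median -0.99, adjusted p = 1.55e-04), and adjusted p = 0.223 with an estimated correlation. Among them Cd274 fell from 141 ± 12.7 to 55.1 ± 16.2 TPM, the costimulatory ligand gene Cd80 from 65.1 to 17.8 TPM and the nitric oxide synthase gene Nos2 from 50.4 to 10.0 TPM. Type I interferon-stimulated genes fell in 17 of 23 and rose in 1, 19 and 1 adjusted over the list alone (median -0.84, adjusted p = 1.35e-08), and adjusted p = 0.458 with an estimated correlation, with Isg15 going from 224 to 59.8 TPM.

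T cell markers fell as a list (median -0.66, adjusted p = 7.09e-05), and adjusted p = 0.526 with an estimated correlation. Of these, 4 of 14 fell over all genes and 13 adjusted over the list alone. Cd8a itself measured 582 ± 11.4 and 409 ± 142 TPM and did not pass (adjusted p = 0.0925), with 285, 378 and 564 TPM in mannose 1, 2 and 3 against 570 to 591 TPM in controls. Without mannose 3 it passed (adjusted p = 0.00499), as did Ifng (adjusted p = 0.00445) and Prf1 (adjusted p = 0.00156). That fit leaves mannose 1 and 2, which shared their receptor V segment use and may not be independent samples. These p-values may thus rest on fewer samples than libraries. Of 17 alternatives, the removal of mannose 3 included, Cd8a passed in 3 (lowest adjusted p = 0.00239), Ifng in 2 (0.00109) and Prf1 in 2 (0.00156). The T cell receptor complex genes Cd247 (116 to 74.6 TPM) and Cd3d (224 to 141 TPM) fell. Effector genes fell in 7 of 19 both ways (median -0.76, adjusted p = 3.31e-06), and adjusted p = 0.458 with an estimated correlation. The cytokine gene Tnf fell from 59.4 to 15.4 TPM, and the granzyme genes Gzmf from 1047 to 359 TPM and Gzmc from 841 to 435 TPM. Tnf is also on the NF-kappaB inflammatory list, and the control libraries held myeloid RNA, so its fall is not shown to lie in T cells. Exhaustion genes fell in 6 of 18, and 7 adjusted over the list alone (median -0.48, adjusted p = 5.44e-04), and adjusted p = 0.581 with an estimated correlation. Examples are the ectonucleotidase gene Entpd1 (142 to 79.5 TPM), the nuclear receptor gene Nr4a3 (78.5 to 30.0 TPM) and the inhibitory receptor gene Havcr2 (137 to 83.1 TPM). The calls of Gzmb (adjusted p = 0.0280), Pdcd1 (adjusted p = 0.0330), Havcr2 and Cd3d were each lost with control 1, 2 or 3 or mannose 1 or 2 left out. The adjusted p then rose up to 0.102 for Gzmb, 0.108 for Pdcd1, 0.0847 for Havcr2 and 0.131 for Cd3d. Cd247 was lost without control 1 or 3 or mannose 1 or 2 (up to 0.0690). With like libraries averaged, the calls of Gzmb, Pdcd1, Havcr2, Cd3d, Cd247, Entpd1 and Nr4a3 were lost. Scaled to the T cell markers, Gzmb (log2 -0.37) and Pdcd1 (-0.17) no longer passed, nor did Gzmc, Entpd1, Havcr2 and Cd3d, and Cd247 (0.05) and Cd8a (0.14) turned positive. With all 16 samples in one fit, Gzmf (adjusted p = 0.0562), Gzmc (0.148), Gzmb (0.216), Pdcd1 (0.312), Entpd1 (0.0958), Havcr2 (0.128), Cd3d (0.296) and Cd247 (0.209) did not pass. With no filter on low values Gzmb, Pdcd1, Havcr2 and Cd3d were lost (up to 0.103).

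Memory genes did not pass as a list (median -0.40, adjusted p = 0.0533), but 5 of 18 fell and 2 rose both ways of adjusting. The list passed, as lower, in 6 of 16 alternatives. These were no filter on low values (adjusted p = 0.0414), the replicate number as a block (0.0415), mitochondrial, haemoglobin, immunoglobulin and receptor segment genes left out (0.0469), scaling to the T cell markers (0.00554) and the removal of control 1 (0.0388) or mannose 3 (0.0362). Il7r, the interleukin-7 receptor gene, fell from 99.8 ± 15.6 to 30.5 ± 15.7 TPM and the chromatin organizer gene Satb1 from 45.1 to 20.9 TPM, while the transcriptional inhibitor gene Id3 rose from 11.5 to 49.0 TPM. Tcf7, a factor of stem-like T cells, rose from 20.6 ± 2.63 to 26.6 ± 0.934 TPM (adjusted p = 0.0492), a call lost without any 1 library but control 3 (adjusted p up to 0.151). Whole tumours held Tcf7 at a level close to that of control CD8 libraries, although Cd8a averaged only 1.72 TPM in them. The rise is thus not shown to lie in T cells. CD4 and regulatory T cell markers fell in 5 of 7, and 6 adjusted over the list alone (median -0.80, adjusted p = 0.00117), and adjusted p = 0.458 with an estimated correlation. Cd4 fell from 13.7 to 5.93 TPM. The members Foxp3, Il2ra and Tnfrsf4 were lost with like libraries averaged and without each single library but mannose 3 (adjusted p up to 0.0920, 0.0847 and 0.113). MHC class I genes fell as a list (median -0.33, adjusted p = 5.61e-04), and adjusted p = 0.581 with an estimated correlation, with 3 of 16 over all genes and 0 adjusted over the list alone. The list call was lost after quantile normalization (adjusted p = 0.106) and when scaled to the T cell markers (adjusted p = 0.282). Those members, Psmb8 (571 to 350 TPM), Tap1 and Psmb9, parts of peptide processing, were lost without each library but mannose 3 (adjusted p up to 0.0848, 0.104 and 0.134), and Tap1 (log2 0.10) and Psmb9 (0.20) turned positive when scaled to the T cell markers. Interferon-gamma-induced genes rose in 3 of 20 and fell in 5, 4 and 6 adjusted over the list alone, and did not pass (adjusted p = 0.0884), except with the block (0.0462), with array weights (0.0129) and without mannose 3 (0.00251), each time as lower. Ido1, a tryptophan-degrading enzyme, rose from 6.17 to 25.8 TPM, and the chemokine gene Cxcl10 fell from 83.1 to 38.5 TPM. With like libraries averaged, the calls of Il7r, Satb1, Id3, Tcf7, Psmb8, Tap1, Psmb9 and Cxcl10 were lost. Scaled to the T cell markers, Satb1, Cxcl10, Cd4, Foxp3 and Tnfrsf4 no longer passed, nor did Psmb8. After quantile normalization the calls of Pdcd1, Cd3d, Tcf7, Psmb8, Tap1, Psmb9, Tnfrsf4 and Cdh5 were lost, and that of Tcf7 also after median-ratio scaling and with the replicate number as a block. Tcf7, Cxcl10, Psmb8, Tap1, Psmb9, Foxp3 and Tnfrsf4 did not pass with all 16 samples in one fit (adjusted p from 0.0753 to 0.560). All of these but Cxcl10, and Il2ra, were lost with no filter on low values (0.0574 to 0.0973). Ifng (128 ± 21.6 and 80.9 ± 48.8 TPM), Prf1 (887 ± 31.3 and 633 ± 315 TPM), Tox (49.5 and 42.6 TPM), Mki67 (41.7 and 43.9 TPM) and Mpi (8.14 and 9.26 TPM) did not pass. Of 17 alternatives, Mki67 passed in 1 (adjusted p = 0.0310) and Mpi in 1 (0.0390), both as higher.

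Matrix genes rose in 18 of 20 and fell in 1 both ways of adjusting (median 1.65, adjusted p = 1.11e-04), and adjusted p = 0.581 with an estimated correlation. Fibronectin, Fn1, rose from 350 ± 119 to 1300 ± 263 TPM and the collagen crosslinker gene Loxl2 from 20.3 to 107 TPM, while Thbs1, a thrombospondin that macrophages also make, fell from 820 to 167 TPM. Fibroblast markers rose in 6 of 10 both ways (median 1.00, adjusted p = 0.0311), and adjusted p = 0.615 with an estimated correlation, and endothelial markers in 5 of 10 both ways (median 1.02, adjusted p = 0.0356), and adjusted p = 0.691 with an estimated correlation. The fibroblast call was lost without mannose 1 (adjusted p = 0.0691) and when scaled to the T cell markers (adjusted p = 0.132). Its members Dcn, Pdgfra, Pdgfrb and Dpt were lost with like libraries averaged. Pdgfra was also lost without control 3 or mannose 1 (adjusted p up to 0.0668), Pdgfrb without mannose 1 or 2 (0.0689) and Dpt without control 3 or mannose 1 or 2 (0.0751). Of the endothelial members, Egfl7, Tie1 and Cdh5 were lost with like libraries averaged, and Tie1 and Cdh5 also without each library but mannose 3 (adjusted p up to 0.106 and 0.120). With all 16 samples in one fit Pdgfra (0.0771) and Dpt (0.521) were lost, and with no filter on low values Tie1 (0.0747) and Cdh5 (0.0836). For the list as a whole, the endothelial call was lost without mannose 1, mannose 2 or control 3 (adjusted p up to 0.0737), scaled to the T cell markers (adjusted p = 0.138) or with like libraries averaged (adjusted p = 0.0617). Ribosomal protein genes rose in 8 of 28 both ways (median 0.19, adjusted p = 0.0364), and adjusted p = 0.760 with an estimated correlation, a call lost without each library but mannose 3 (adjusted p up to 0.131) and with like libraries averaged (adjusted p = 0.240). The ribosomal call was also lost after median-ratio scaling (adjusted p = 0.271) and scaled to the T cell markers (adjusted p = 0.178). Nuclear-encoded respiratory chain genes fell in 5 of 26, 3 adjusted over the list alone (median -0.04, adjusted p = 0.0364), and NRF2 antioxidant genes fell in 4 of 15 and rose in 3 both ways (median -0.16, adjusted p = 0.0364); each had adjusted p = 0.458 with an estimated correlation. The antioxidant call was lost without control 3 (adjusted p = 0.0541) and the respiratory call without control 3, mannose 1 or mannose 3 (adjusted p up to 0.0631). Both were also lost after quantile normalization, with array weights and when scaled to the T cell markers, with adjusted p up to 0.282 for the antioxidant and 0.847 for the respiratory list, whose median relative to all genes turned to 0.09 after quantile normalization. The respiratory genes Ndufa1 (log2 0.28), Cox5b (0.16), Sdhb (0.23) and Cox5a (0.13) turned positive when scaled to the T cell markers. Cox5a was also lost without control 2 or 3 or mannose 1 or 2 (adjusted p up to 0.101), and Sdhb without mannose 2 (adjusted p = 0.0579), and all 4 genes with like libraries averaged. Ndufa1 was lost with all 16 samples in one fit (0.0565), and Cox5a with no filter on low values (0.0650). Of the 32 lists tested 18 passed camera, 0 passed with an estimated correlation (6 at an unadjusted p under 0.05), and fry called 15 in 1 direction. These included fatty acid oxidation (adjusted p = 0.00606), hypoxia (0.0151), TGF-beta response (0.0156) and immediate-early genes (0.0253), which did not pass camera. Fry did not call the T cell (0.0872), exhaustion (0.135), MHC class I (0.141), matrix (0.0531), fibroblast (0.0588), endothelial (0.0595) and ribosomal lists (0.0531). Its test of change in either direction called 29. At 3 against 3 libraries an exact permutation test of a list level cannot go below 0.1, which 26 of the 40 list levels reached. This floor, too, takes the libraries as independent samples.

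**Figure D2:**
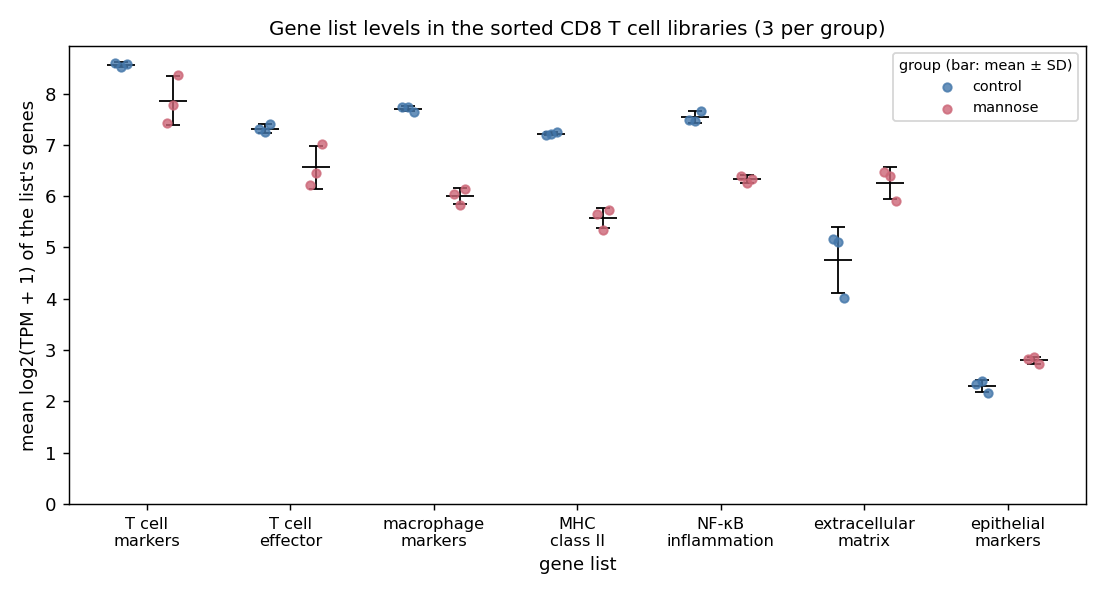
Each point is the mean log2(TPM + 1) of a gene list in 1 sorted CD8 library, by list on the x axis, with bars for mean ± SD of 3 control and 3 mannose libraries. Matrix means are 4.76 in controls and 6.26 with mannose, and MHC class II means 7.21 and 5.57.

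Markers of other cell types showed what the sorted libraries held. Krt8 averaged 1363 ± 242 TPM in whole tumours (SD, n = 10), and its level in the CD8 libraries was 12.6% of that in controls and 64.3% with mannose. The secreted phosphoprotein gene Spp1 stood at 20.6% and 68.4% of its tumour level. Krt19 rose from 101 to 548 TPM and Krt18 from 127 to 622 TPM, whereas Cdh1, the epithelial cadherin, fell by 1.33 on the log2 scale from 28.7 TPM. In all, 3 of the 4 carcinoma markers tested rose and 1 fell, both ways of adjusting. The mesothelial and ovarian cancer antigen Msln rose from 5.73 to 37.4 TPM. Myeloid genes exceeded their tumour level in control CD8 libraries, with Il1b at 2352% and Arg1 at 495%, and stood at 444% and 81.2% with mannose. Cd8a was at 1.72 ± 2.22 TPM in the tumours.

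Beta chain V segments of the T cell receptor, read as shares of their summed TPM over 22 segments, did not follow the groups. Trbv13-1 held 41.2% and 41.7% in control 1 and 2 but 1.15% in control 3, and Trbv12-1 held 11.1% and 12.5% in mannose 1 and 2 but 0% in mannose 3. The shares of control 1 and 2 differed by 4.03% and those of mannose 1 and 2 by 6.39%, while the other 13 pairs of libraries differed by 37.3% to 57.8%.

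**Figure D3:**
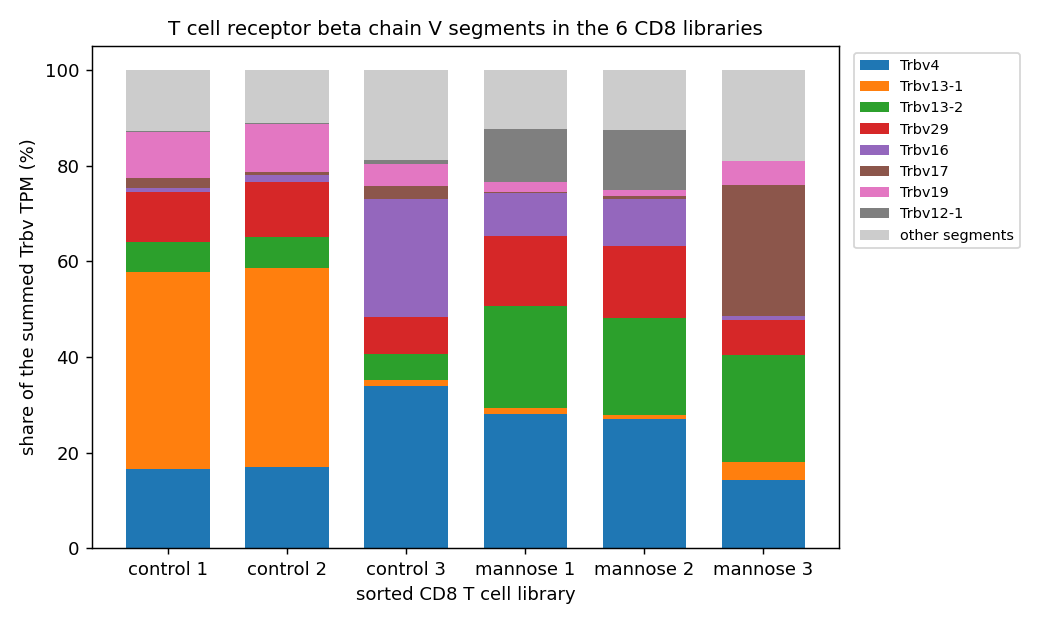
Stacked bars give the share, in percent, of each Trbv segment in the summed Trbv TPM of the 6 CD8 libraries on the x axis. Control 1 and 2 look alike, as do mannose 1 and 2, and Trbv13-1 holds 41.2% in control 1 and 1.15% in control 3.

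Whether the difference between mannose and control was unlike in the sorted CD8 libraries and in whole tumours was tested as an interaction. Control CD8 libraries also held myeloid RNA, with Arg1 at 495% and Csf1r at 265% of the tumour level. The differences are thus not shown to lie in the T cells, and their directions rest on the sample labels. The 5 genes with the smallest p were Ccr1, Trem1, Il1b, Il1r2 and Nol3. The difference of log2 effects, CD8 minus tumour, was -3.09 for the chemokine receptor gene Ccr1, -2.98 for the myeloid receptor gene Trem1, -2.69 for Il1b and -2.32 for Il1r2, and 2.22 for Nol3, an inhibitor of cell death (adjusted p between 6.13e-06 and 7.03e-06). Of the panel, Mrc1 (-2.87, adjusted p = 6.18e-05), Il7r (-2.11, adjusted p = 0.00580) and Gzmb (-2.32, adjusted p = 0.0479) passed. Cd274 (-1.78, adjusted p = 0.0560) and Pdcd1 (-0.95, adjusted p = 0.435) did not. Of 15498 genes 2896 passed, 1712 more positive and 1184 more negative in CD8. The count was 1609 when like libraries were averaged, 1884 without CD8 mannose 1 and 5304 after scaling to the T cell markers. Of 35 lists 15 passed camera, led by macrophage markers (median -2.14, adjusted p = 8.56e-12, and adjusted p = 0.298 with an estimated correlation) and inflammatory genes (median -1.20, adjusted p = 9.03e-10, and adjusted p = 0.0910 with an estimated correlation). Effector genes (median -1.26, adjusted p = 2.68e-05) had adjusted p = 0.738 with an estimated correlation, and 0 lists passed that way, with 3 at an unadjusted p under 0.05.

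Changes were compared across 12481 genes tested in both tissues. No gene passed in both, since 0 passed in the tumours. At an unadjusted p under 0.05, 192 genes were higher in mannose tumours and lower in mannose CD8 libraries against 112.6 expected (Fisher's exact test, odds ratio 2.07, adjusted p = 2.06e-14), and 52 were lower in tumours and higher in CD8 libraries against 25.7 expected (odds ratio 4.10, adjusted p = 1.77e-09). Genes higher in both numbered 157 against 230.8 expected (odds ratio 0.571, adjusted p = 7.03e-10), and 6 were lower in both against 12.5 expected. Arg1 and Mrc1 were among those higher in tumours and lower in CD8 libraries. Log2 changes in the tissues correlated across genes with Pearson's r of -0.194 and Spearman's rho of -0.18, and genes are not independent replicates, so the Fisher p-values overstate the evidence. Of 100 splits of the 10 tumours, the real one included, 23 gave a correlation of at least that size with either sign. In all, 244 genes moved opposite ways against 138.3 expected, with 285 against 167.5 after quantile normalization and 296 against 173.4 after median-ratio scaling. The genes that moved the same way numbered 163, 98 and 99 in these settings.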

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

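Of the tests below, the share of tumour-abundant genes that rose and the splits of the samples for counts of genes and lists were laid down before their results were seen; the tests on the T cell share, on changes within T cells, on column headings, on receptor V segments and on the correlation of changes between the tissues were chosen after.

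The first pattern weighed is that myeloid genes were lower and carcinoma genes higher in the mannose CD8 libraries. A lower share of T cells alone would raise markers of every other cell type, and it is argued against by the macrophage list, whose median log2 change was -1.82 with 14 of 14 members lower while Krt8 and Krt18 rose. Carry-over of carcinoma cells or their RNA through the sort may explain the rises. Of 364 genes abundant in the tumours and at least 2-fold lower in the CD8 libraries, 259 or 71.2% rose past the threshold. This lies between the bounds of 80% and 50% set beforehand. Of all 14280 genes tested, 3306 rose. Among the 364, 91.8% had a positive log2 change and 5 fell past the threshold, with a median of 0.93. In the simulated CD8 fit 64% of genes moved 2-fold were called, so 80% may be out of reach for changes of this size. The share thus cannot decide, and carry-over stays open together with a true shift in the myeloid cells. Exchanged group labels cannot be told apart from a mannose effect, because the columns of all 3 control tables are headed as mannose samples, as are those of the mannose tables, and no value in the tables settles which group a library belongs to. An effect of mannose on the myeloid cells that pass the sort was not tested apart from these.

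The second pattern is that T cell genes were lower in the mannose CD8 libraries. For Cd8a the fall lay mainly in mannose 1 and 2, the pair with like receptor use (285 and 378 TPM, against 564 TPM in mannose 3). A lower share of T cell RNA is a candidate explanation: 183 genes far higher in the CD8 libraries than in the tumours, none of them on a list, had a median log2 change of -0.62, which went to 0.057 (quartiles -0.16 and 0.22) after scaling to the T cell markers. A change within the T cells cannot be told apart from this for most genes. Of 233 genes far higher in the CD8 libraries, list members now included, 9 or 3.86% passed after scaling, adjusted over these genes. With like libraries averaged 6 passed. The 9 genes were higher Fosb, Iffo2, Dsc2 and Calca and lower Serpinb2, Il1a, Il7r, Il12rb2 and Cxcl2; with like libraries averaged Il7r, Il12rb2, Iffo2 and Calca no longer passed (adjusted p of 0.364, 0.518, 0.232 and 0.733) and Cxcl1 did (0.0347). Control CD8 libraries held Il1b at 2352% of its tumour level, so Serpinb2, Il1a, Cxcl2 and Cxcl1 may reflect myeloid RNA, which leaves after averaging Dsc2 and Fosb, the latter among the 7 of 16 immediate-early genes, known to rise when tissue is dissociated, that were higher (Fos from 128 to 334 TPM), and no test separated an effect on T cell number from one on the purity of the sort.

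The third pattern is the likeness of CD8 control 1 and 2, and of mannose 1 and 2, in T cell receptor V segments. A likeness of the whole group is argued against by the largest distance of beta chain shares within a group, 54.0%, against 37.3% for the least distant of the other pairs. A shared animal or pool of cells is a candidate explanation, since the alpha chain segments were also most alike in these pairs (lowest r 0.866, against 0.784 at most in other pairs). If so, each group holds fewer independent samples than libraries, and 1091 genes rose and 561 fell with the pairs averaged. The labels name no animals, so this stays a hypothesis, and no biological explanation was tested.

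Other splits of the same samples were counted. For tumour genes past the threshold by limma the real count was 0, which all 100 of 100 splits reach by necessity, so that comparison says nothing about chance; 18 of the other splits called at least 1 gene (highest other 594), and 827 genes had an unadjusted p under 0.05 in the real split. That count of 827 was reached by 18 of 100 splits, so chance cannot be excluded for it, and the highest other, 3811, several times the real count, may point to a structure of the samples, which was not tested. The 12 tumour lists were reached by 50 of 100 splits (highest other 18), and chance cannot be excluded. In CD8 T cells 1 of 10 splits, the real one, reached 4980 genes (highest other 3), and 1 of 10 reached 18 lists (highest other 16); 10 splits are too few for a share under 0.05. For the difference between tissues 4 of 100 splits gave at least 2896 genes (highest other 2954). Of these, 3 were among the 6 other splits that keep the CD8 groups together, and the 93 that mix them gave at most 19. The count thus followed the CD8 groups, whose 10 splits are too few for a share under 0.05, and chance is not excluded for the tumour side of the difference. The correlation of tumour and CD8 changes across genes (r = -0.194) was reached in size by 23 of 100 splits of the tumours (highest other 0.256), so chance cannot be excluded for it.

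Single tumours stood far from the other 4 of their group in 16 of 132 sets of values, where chance gives about 1 in 20, or 6.6. Control 1 was lowest in the memory (1.88), NF-kappaB inflammation (3.61), TGF-beta response (3.26) and immediate-early lists (4.41, mean log2(TPM + 1) each) and in symbols with at least 1 TPM (12345, others 13222 to 13429). Mannose 3 was highest in matrix (7.59), TGF-beta response (4.39), B cell (0.944), macrophage (7.35) and adipocyte lists (2.16). Mannose 4 was lowest in respiratory chain genes (7.21) and in Npl (26.5 TPM, others 33.5 to 35.0). Mannose 1 was highest in hypoxia genes (6.08) and lowest in Efemp1 (17.7 TPM, others 27.3 to 30.8). Control 3 was highest in Adamdec1 (12.8 TPM, others 5 to 6.56) and lowest in Efemp1 (32.5 TPM, others 38.1 to 39.3).

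Effects of mannose differed between the sorted CD8 libraries and the tumours for 2896 genes by the interaction test. The CD8 minus tumour differences in log2 were -3.09 for Ccr1, -2.98 for Trem1, -2.87 for Mrc1, -2.69 for Il1b, -2.32 for Il1r2, -2.32 for Gzmb, -2.11 for Il7r and 2.22 for Nol3. By list medians they were -2.14 for macrophage, -2.02 for MHC class II, -1.40 for checkpoint, -1.27 for neutrophil, -1.26 for effector, -1.20 for inflammatory, -1.14 for CD4, -1.05 for T cell, -0.86 for type I interferon, -0.85 for dendritic cell and -0.84 for exhaustion genes. Positive medians were found for epithelial (2.61), endothelial (1.19), matrix (0.91) and ribosomal genes (0.24). These 15 of 35 lists passed camera, 18 had an unadjusted p under 0.05, and 0 passed with an estimated correlation (3 at an unadjusted p under 0.05).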

How the results depend on the processing

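Median-ratio scaling, array weights, the removal of both tumour libraries that stood apart, scaling to T cell markers and averaging of like CD8 libraries were chosen after the data were seen, as was the narrowing of list values to called lists, relative to the median of all genes, once many uncalled lists were found to change sign. Count-based alternatives (DESeq2, limma-voom with or without quality weights, RLE and upper-quartile factors, glmTreat) were not run because the files hold no counts. The cause of each change below was not tested, unless given.

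In the CD8 libraries 69 of 154 named genes kept their direction and their side of the threshold in each alternative. So did 12 of 18 lists by camera with the preset correlation. Camera compares a list with other genes, and scaling to the T cell markers moves all genes of a library together. That setting therefore tests list calls little. It also makes the T cell markers nearly equal between libraries. Their kept call there reflects the median of all genes, 0.72, and is no evidence that T cell genes stayed lower. With an estimated correlation 0 lists passed (6 at an unadjusted p under 0.05). Fry's test of change in 1 direction called 15 lists. Of the 12 lists kept by camera, it did not call T cell markers (adjusted p = 0.0872), exhaustion (0.135) or matrix genes (0.0531). The 5 interaction genes with the smallest p kept their direction and their side of the threshold in each alternative. Of 20 tumour genes 14 did, and of 12 tumour lists 1, skeletal muscle. Tumour lists numbered 0 with an estimated correlation (1 at an unadjusted p under 0.05), 6 with no filter and 5 after quantile normalization. By fry they numbered 0 for change in 1 direction (0 unadjusted) and 1 for change in either direction. Tumour genes higher numbered 0 to 1 with a library left out (1 without mannose 4).

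CD8 genes higher and lower numbered 5114 and 3517 with array weights and 6876 and 384 scaled to T cell markers, which by construction raises mannose values where the markers were lower. They numbered 1091 and 561 with like libraries averaged, which leaves fewer samples, and 3152 and 1686 with the replicate number as a block. With a library left out they ranged from 1909 to 3610 and from 894 to 2509, lowest without mannose 2. Interaction genes numbered 1609 averaged, 5304 scaled, and 1884 to 4010 with a library left out, lowest without CD8 mannose 1 and highest without tumour control 1. Genes shared by both tissues numbered 407 at an unadjusted p; of these 163 moved the same way, against 98 after quantile normalization and 99 after median-ratio scaling, neither of them planned for this comparison.

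In the tumours, none of the panel genes that changed sign passed in any setting. Quantile normalization turned Pdcd1 (-0.092), Tcf7 (-0.086) and Mpi (-0.060), median-ratio scaling Tcf7 (-0.061) and Mpi (-0.018), and array weights Tcf7 (-0.018). Without control 1 and mannose 3 together, Cd8a (-0.55), Pdcd1 (-0.59), Cd274 (-0.16), Tcf7 (-0.024), Il7r (-0.022) and the ribosomal list (0.0046) turned. With a library left out, Cd8a ranged from -0.32 to 0.40, Pdcd1 from -0.30 to 0.36, Tcf7 from -0.062 to 0.11, Mpi from -0.011 to 0.23 and the endothelial list from -0.31 to 0.0044. The epithelial level turned to 0.0828 as a median of genes.

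In CD8 T cells, quantile normalization turned Mpi (-0.053) and the respiratory list (0.093), and median-ratio scaling Mki67 (-0.014), which ranged from -0.051 to 0.19 with a library left out. Scaling to T cell markers turned Tap1 (0.10), Psmb9 (0.20), Eno1 (0.12), Ndufa1 (0.28), Cox5b (0.16), Sdhb (0.23), Cox5a (0.13), Slc25a20 (0.27), Mvd (0.13), Sdf2l1 (0.075), Taldo1 (0.078), Cd247 (0.049), Cd8a (0.14), Prf1 (0.11) and Tox (0.44). Marker levels as medians turned for mast cells (0.0414), adipocytes (-0.0916) and muscle (0.0714).

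Whether replicate numbers pair the samples was not settled. The correlation of deviations between same-numbered libraries was -0.0548, -0.232, 0.280, 0.161 and -0.511 in tumours and 0.0565, 0.0948 and 0.163 in CD8 T cells. Among the mannose libraries, the same-numbered one correlated best with tumour controls 3 and 4 and with CD8 controls 1 and 3. With so few libraries per group, pairing is neither shown nor excluded. Read depth is unknown, so what it limits could not be measured.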

Other observations

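Both correlations given last were laid down before their results were seen. The gene lists below were fixed at the same time. In the tissue for which each is described here none passed camera with the settings of the report, and the alternatives in which one did are given. By fry, the fatty acid oxidation, hypoxia, TGF-beta response and immediate-early lists passed in the CD8 libraries (adjusted p from 0.00606 to 0.0253).

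Genes of sugar and fat metabolism moved both ways in the mannose CD8 libraries. Of 26 mannose and glycosylation genes, 6 rose and 3 fell (7 and 5 adjusted over the list alone). Fut8, which adds core fucose to glycans, rose from 27.5 ± 7.14 to 65.4 ± 4.69 TPM (SD, n = 3), the mannosyltransferase gene Alg2 from 9.99 to 21.8 TPM and the mannosidase gene Man1a from 32.9 to 44.7 TPM, while Man2a1 fell from 41.3 to 21.8 TPM. The list's median of 0.03 and mean of 0.06 were positive and its camera direction was down (adjusted p = 0.682). Of 20 glycolysis genes, 6 rose and 3 fell both ways of adjusting (median 0.07, adjusted p = 0.917). The phosphofructokinase gene Pfkm rose from 10.8 to 25.5 TPM, and the lactate exporter gene Slc16a3 fell from 224 to 95.0 TPM. Of 16 fatty acid oxidation genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.28, adjusted p = 0.176), with the acyl-CoA dehydrogenase gene Acadvl rising from 44.2 to 63.7 TPM. The list passed, as higher, with no filter on low values (adjusted p = 0.0303) and after quantile normalization (0.0341). The calls of Man1a, Man2a1 and Acadvl were lost with like libraries averaged, and those of Man1a and Man2a1 with all 16 samples in one fit (0.191 and 0.0528). Of 19 cholesterol genes, 3 rose and 1 fell both ways (median -0.11, adjusted p = 0.394), with the squalene epoxidase gene Sqle rising from 23.7 to 38.9 TPM. The other 3 calls were lost with like libraries averaged (Mvd, Insig1, Fdft1), and 2 of them also without control 2 or mannose 2 (Insig1, adjusted p up to 0.0603) or control 2 or mannose 1 (Fdft1, 0.0704). With all 16 samples in one fit the 3 were lost too (0.0525 to 0.125).

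Stress and signalling lists were mixed too. Hypoxia genes rose in 8 of 18 and fell in 2 (10 and 3 adjusted over the list alone; median 0.40, adjusted p = 0.0537), with the collagen hydroxylase genes P4ha2 rising from 12.6 to 57.3 TPM and Plod2 from 25.4 to 73.3 TPM. The list passed, as higher, in 6 of 16 alternatives, which were no filter on low values (0.0126), quantile normalization (0.00781), the replicate number as a block (0.0483), array weights (0.0129) and the removal of control 3 (0.0398) or mannose 3 (0.0114). TGF-beta response genes rose in 5 of 12 and fell in 3 (6 and 3 adjusted over the list alone; median 0.49, adjusted p = 0.526). The matrix protein gene Tgfbi fell from 281 to 65.8 TPM. Immediate-early genes rose in 7 of 16 and fell in 2 both ways (median 0.15, adjusted p = 0.639), with Jun rising from 60.5 to 168 TPM and Fos from 128 to 334 TPM. Unfolded protein response genes rose in 3 of 19 and fell in 1 (2 and 0 adjusted over the list alone; median 0.07, adjusted p = 0.859), and Trib3, Asns, Sdf2l1 and Pdia6 were lost with like libraries averaged. Single libraries also ended the calls of Asns (control 1 or 2 or mannose 1 or 2, adjusted p up to 0.0846), Sdf2l1 (control 2 or 3 or mannose 1 or 2, 0.0960) and Pdia6 (each library but mannose 3, 0.136). Pdia6 was also lost with all 16 samples in one fit (0.0557), and with Sdf2l1 when no filter was used (0.0777 and 0.0631). Among cell cycle genes, 1 of 23 rose, the mitotic kinase gene Plk1, and 0 adjusted over the list alone (median 0.14, adjusted p = 0.639); 4 single libraries decided that call, control 1, 2 and 3 and mannose 2 (adjusted p up to 0.0819), and it was lost with like libraries averaged, with all 16 samples in one fit (0.260), after quantile normalization and with the replicate block. Mitochondrially encoded genes rose in 2 of 13 and 0 adjusted over the list alone (median 0.004, camera down, adjusted p = 0.859). Both, mt-Cytb and mt-Nd4, were lost without each library but mannose 3 (adjusted p up to 0.118 and 0.143), with like libraries averaged, with the replicate number as a block, after quantile or median-ratio scaling, with all 16 samples in one fit (0.0967 and 0.169) and with no filter on low values (0.155 and 0.147).

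Markers of further cell types in the CD8 libraries were few. Basophil and mast cell markers rose in 1 of 5 both ways, Mcpt8 going from 10.2 to 20.5 TPM (list median -0.10, adjusted p = 0.859), and muscle markers fell in 1 of 5 both ways (median -0.02, adjusted p = 0.540). Lists with fewer than 5 tested genes had no list test. Both ways of adjusting, B cell markers fell in 2 of 4, skin markers rose in 2 of 4, erythroid markers in 1 of 3, the mesothelial marker Msln and the acinar marker Cela1 (19.0 to 38.3 TPM) rose, and by limma 0 of 4 natural killer markers passed. The adipocyte marker tested did not pass over all genes and rose adjusted over the list alone. The B cell calls were lost with single libraries left out, Cd79b without control 2 or mannose 1 or 2 (adjusted p up to 0.0589) and Cd22 without control 1 or 3 or mannose 1 or 2 (up to 0.0932). The erythroid call, Hba-a2, was lost without control 1 or 3 or mannose 1 or 2 (adjusted p up to 0.114), and the skin gene Krt10 without mannose 1 or 2 (up to 0.0525). With like libraries averaged, Cd79b, Hba-a2, Krt10, the other skin gene, Sbsn, and the muscle gene Tnni2 were lost. Scaled to the T cell markers, Man2a1, Cd79b, Cd22 and Tnni2 were lost. Cd22, Tnni2 and Hba-a2 were lost with all 16 samples in one fit (0.226, 0.496 and 0.318), and Cd22 and Hba-a2 with no filter on low values (0.0811 and 0.0910), where the B cell list had enough genes to be tested and passed as lower (0.0149).

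In the tumours the lists not described so far did not pass with the settings of the report. Medians were 0.07 for mannose and glycosylation genes (camera down, adjusted p = 0.542), 0.03 for respiratory chain genes (camera down, 0.108), 0.01 for fatty acid oxidation (camera down, 0.0879) and 0.20 for cholesterol genes (0.201). They were 0.05 for hypoxia (camera down, 0.116), 0.06 for NRF2 (camera down, 0.635), 0.26 for TGF-beta response (0.542), 0.19 for MHC class II (0.882), 0.15 for dendritic cell (camera down, 0.892) and 0.49 for fibroblast genes (0.283). Mitochondrially encoded genes had a median of 0.17, a mean of -0.04 and a camera direction of up (0.875). Of 19 alternatives, respiratory chain genes passed as lower than all genes after median-ratio scaling (0.00829) and without control 2 (0.0478), control 5 (0.0104) or mannose 5 (0.0487). Fatty acid oxidation genes did so after median-ratio scaling (0.0255), and hypoxia genes without control 3 (0.0184) or mannose 1 (0.00160). Cholesterol genes passed as higher with array weights (2.41e-04), without control 3 (0.00744), mannose 3 (0.00417) or mannose 4 (0.0453) and without control 1 and mannose 3 together (0.00725). Fibroblast genes passed as higher with the replicate number as a block (0.00933) and without control 3 (0.0357) or mannose 1 (0.0115). Natural killer, B cell, adipocyte, skin, mesothelial and acinar markers had too few genes tested. Levels of acinar markers were 0.939 in control and 0.999 in mannose tumours (exact permutation test, p = 0.0317, not adjusted over the 40 list levels compared), and did not differ as medians of the list's genes (difference 0, p = 1). Natural killer levels were 0.469 and 0.720 (exact permutation test, p = 0.135, and p = 0.0476 as medians).

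Across the 10 tumours, a hypothesis that those with more T cell mRNA hold more interferon-gamma-induced mRNA was tested on list levels, as 1 of 2 relations. Pearson's r was 0.941 (permutation p = 5.0e-05, adjusted p = 1.0e-04) and Spearman's rho 0.903 (permutation p = 6.9e-04, adjusted p = 0.00138). Without mannose 3 and control 1, the tumours farthest from the median T cell level, r was 0.883. The correlation of deviations from the group means was 0.941, so the relation may hold in both groups. Macrophage levels followed T cell levels with r = 0.875 (permutation p = 0.00147) and rho = 0.758 (permutation p = 0.0144), and with 0.886 for deviations from the group means. Without the same 2 tumours r was 0.495. Their removal also narrows the range of T cell levels, so how far that relation rests on them cannot be told. With them kept, r was 0.799 within the control and 0.942 within the mannose tumours.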
